A study of Mus musculus with 25 samples.

How the data were processed

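Total RNA of sorted mouse thymocytes was isolated with RNAzol B, copied into biotin-labelled cRNA with the Ambion MessageAmp kit and hybridised to Illumina bead arrays, per the labels' protocols. The series held 25 samples on 25 arrays of 5 chips. Each sample's group was taken from its source label, and its chip from the barcode in its title, which counts as the only batch the labels gave. The scanner, its software and the genome build behind the probes are not given in the sources used here.

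The deposited table of non-normalized values held the mean bead brightness of 46237 probes as an intensity on a linear scale, with no background subtracted and no scaling between arrays, as the values show. Each deposited intensity had a detection p-value beside it, whose test is not given in the sources used here. These detection p-values fell far below what a rank among negative control probes can give, so the background that was estimated from them rested on an assumption about that test. The authors also deposited a table of log2 values, which had equal quartiles on every array and so had been quantile normalized. Each of its columns followed the log2 intensity of the same sample with a correlation of at least 0.995, and all its medians were 6.51. That table served as an alternative.

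Intensities were background-corrected and quantile normalized with neqc of limma 3.58.1 in R 4.3.3, which estimates the background from the detection p-values, adds an offset of 16 and takes log2. The offset draws dim probes toward a floor, so fold changes of dim genes are understated. A probe was kept when its detection p-value was below 0.05 on at least 3 arrays, which left 30174 probes. Probe names came from the platform's annotation table: 35784 probes had 1 gene symbol, 0 had several and 10453 had none and are unnamed here. Of the named probes, 28620 were matched to a current RefSeq gene by gene identifier and 2637 by transcript accession, which changed 937 symbols. The RefSeq table describes GRCm38.p6. Since the files name no genome build, its coordinates are not printed, and it was used for names and for which genes lie near each other. Where a gene had several kept probes, the one with the highest mean log2 value over all arrays stood for it, which left 15533 genes. Genes with several probes are said below to have probes that disagreed where at least 1 had the opposite sign. Unnamed probes were tested apart from the genes.

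All 25 arrays entered 1 limma model with a mean per group and the chip as a random block (duplicateCorrelation, statmod 1.5.0; correlation within chips 0.00457), followed by eBayes. One estimate of the spread for all groups was needed because the TN2 and TN3 groups had 2 arrays each. Tests were two-sided, p-values were adjusted by Benjamini and Hochberg over the genes, and genes with an adjusted p below 0.05 are called higher or lower. Values are log2 fold changes ± standard error (SE) from this model, or group means ± SD over arrays. A gene not detected on any array of a group has only a bound there: its fold is given as at least the ratio of the other group's mean to the mean of the lowest detected signal per array, or the gene's own signal where that was higher. The labels do not say whether the samples of a group came from separate mice, so p-values measure the spread between these samples. For arrays, their number limits the precision.

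A set of 28 gene lists was fixed before the data were examined, 1 of them for checking labels and not counted below. Each list was tested with limma's cameraPR, with a preset inter-gene correlation of 0.01 and adjustment over the lists of a comparison. The test was repeated with the correlation estimated from the residuals and with fry. Members past the threshold were counted both ways, adjusted over all genes and adjusted over the list alone. The stage score of an array was the mean log2 value of the list of TN3 and beta-selection genes minus that of the list of early progenitor and TN2 genes, compared between groups by an exact two-sided permutation test. Named genes followed a rule fixed beforehand: the label checks, then the 10 largest rises and 10 largest falls among called genes whose group values did not overlap and whose sign was the same in each chip that held both groups, then up to 4 members per list with the smallest adjusted p. Predicted genes without a name were skipped. Genes named outside this rule are said to be so.

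The model was tested on simulated data, with 200 genes changed by known folds in arrays drawn around the real means and spreads. With 6 arrays against 6, the test found 43.3% of 1.5-fold, 80.6% of 2-fold and 100% of 4-fold changes. The comparison of 9 arrays with the 6 young ones found 56.7%, 89.6% and 100%, and that of 9 arrays with the 6 arrays of old cells with competition 50.7%, 88.1% and 100%. With 2 arrays against 2, it found 16.4%, 35.8% and 86.4%. Alternatives were fixed in advance for the background correction, normalization, source of values, detection filter, probes per gene, chip term, samples in the model, array weights, variance model, fold threshold and each array left out in turn. Figures were drawn with matplotlib 3.10.9.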

Results

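The series compared thymocytes of the CD4-, CD8- and CD3-negative compartment that carried CD25, the alpha chain of the IL-2 receptor. These cells pass from the TN2 stage, where CD44 is still present, to the TN3 stage, where the T cell receptor beta locus is rearranged. Its stated comparison was between young cells, old cells with competition and old cells without competition. The young cells (n = 6) were the hosts' own C57BL/6 cells with the CD45.2 allele. Old cells with competition (n = 6) were B6/Ly5.1 cells of donor origin with the CD45.1 allele, taken from wild-type hosts that the labels call competitive. Old cells without competition (n = 9) came from F1(WB x B6/Ly5.1) donors in hosts without Rag2 and the common cytokine receptor gamma chain and with mutated Kit; the labels call these hosts non-competitive. One of these 9 samples had no cell-type label. TN2 (n = 2) and TN3 (n = 2) cells of wild-type B6/Ly5.1 mice gave the ends of the stage scale. Young cells and old cells with competition shared chips 2 and 4, with 3 arrays each on both, whereas old cells without competition lay on chips 1 and 5. Between 46.7% and 50.1% of the probes were detected on the young arrays, 46.8% to 49.4% in old cells with competition, 41.1% to 45.7% in old cells without competition, 43.9% to 44.6% in TN2 and 43.1% to 44.2% in TN3.

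The genes behind the labels were read first. Cd44, which marks TN2 cells, stood at 6.34 ± 0.37 (log2, SD, n = 2) in TN2 and 4.46 ± 0.00 in TN3, and at 5.68 ± 0.44 in young cells (n = 6), 4.48 ± 0.19 in old cells with competition (n = 6) and 4.55 ± 0.13 in old cells without competition (n = 9). Kit, the receptor for stem cell factor, was at 7.61 ± 0.17, 5.69 ± 0.13, 6.90 ± 0.28, 4.62 ± 0.61 and 4.78 ± 0.52 in these groups, so that both old groups lay below TN3. Il2ra, which encodes CD25, lay near the floor of the array, at 5.43 ± 0.21 in young cells and 4.75 ± 0.35 in old cells with competition. It was at 4.62 and 4.42 on the TN2 arrays and at 4.40 and 4.13 on the TN3 arrays. These cells carry CD25 too, so a low Il2ra value here does not show a loss of CD25. Il2rg and Rag2, the genes disrupted in the hosts without competition, were detected on 7 and 6 of the 9 arrays of donor-derived cells from those hosts and on all 6 young arrays. Their differences from young cells did not pass (-0.81 ± 0.32, adjusted p = 0.123; 0.05 ± 0.30, adjusted p = 0.952). Ptprc, which encodes CD45, did not differ between old cells with competition and young cells beyond the spread (0.20 ± 0.18, adjusted p = 0.793). Whether its array probes can separate the alleles was not tested. One array of old cells with competition, number 6, stood apart: 2304 genes lay over 1 log2 unit from the mean of its group, against 85 to 185 on the group's other arrays. Cd4 was at 8.86 there and Rag1 at 11.1.

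TN3 cells were compared with TN2 cells to obtain the stage difference on the same arrays. Lef1, a transcription factor of early T cells, rose most (4.37 ± 0.46 log2 ± SE, n = 2 against 2, adjusted p = 7.66e-06). Cd3d, a chain of the CD3 complex, rose by 2.44 ± 0.22 and the recombinase gene Rag1 by 2.32 ± 0.36. The largest falls included the beta-globin gene Hbb-b1 (-5.49 ± 1.10), the mast cell protease gene Cpa3 (-3.72 ± 0.56) and Tyrobp, the adaptor of myeloid and NK cell receptors (-3.48 ± 0.41). In all, 181 of 15533 genes passed, 59 higher and 122 lower in TN3; this split rested on single arrays, since 22 were higher and 103 lower without TN2 array 1, 46 and 146 without TN2 array 2, 73 and 57 without TN3 array 1, and 66 and 79 without TN3 array 2. The other large rises were Scn4b, Slc5a9, Ets2, Camsap2, Ly108 and Nudcd3 (2.17 to 3.54). Hdgfrp3, not detected in TN2, was at least 7.58-fold higher. Serpinf1, Ier3, Igfbp4 and Serpine2 fell by 2.79 to 3.08, and 3 genes without detection in TN3 were at least 11.4-fold (Napsa), 5.94-fold (Emilin2) and 5.86-fold (Cd180) lower. Leaving out 1 of the 4 arrays ended the calls of Hbb-b1, Scn4b, Ets2, Ly108, Nudcd3, Hdgfrp3 and Ier3 (adjusted p up to 0.301, for Ets2), and the difference of Cd180 shrank without TN2 array 1 but still passed (adjusted p = 0.0127).

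By list, the early progenitor and TN2 genes fell from TN2 to TN3: of 17 measured members 8 fell and 9 did not pass, and 8 fell when adjusted over the list alone (adjusted p = 4.2e-18). Kit fell by 1.92 ± 0.45, Cd44 by 1.88 ± 0.26 and the homeobox gene Hhex by 2.00 ± 0.33. Of the 19 TN3 and beta-selection genes 4 rose, and 11 rose adjusted over the list alone (adjusted p = 5.09e-19). They included Ptcra, the alpha chain of the pre-T cell receptor (1.99 ± 0.43). The T-cell leukaemia oncogenes (4 of 11 fell; 5 fell and 2 rose adjusted over the list alone) and the myeloid and dendritic cell genes (2 of 19 fell; 4 adjusted over the list alone) were lower too (adjusted p = 3.28e-05 and 0.000785). Among these were Lyl1 and Mpo, not detected in TN3 and at least 4.21-fold and 5.36-fold lower. The remaining lists lost their call when the correlation was estimated. The Notch targets were higher (2 of 11 rose, and 4 rose and 1 fell adjusted over the list alone; adjusted p = 0.0189, or 0.171 with an estimated correlation), with Dtx1 at 2.16 ± 0.47. The mitosis list was lower with 1 member, Cenpa (-0.96 ± 0.23), past the threshold (4 of 21 adjusted over the list alone; adjusted p = 6.11e-06, or 0.139 with an estimated correlation). The immediate early genes were lower with 2 of 14 fallen, Fos by 1.80 ± 0.37 and Ier3 (4 adjusted over the list alone; adjusted p = 0.00135, or 0.0915 with an estimated correlation). The DNA replication genes were lower as a list, with 0 of 24 members past the threshold either way (adjusted p = 0.048, or 0.692 with an estimated correlation). When the 4 arrays were fitted without the other groups, 0 genes passed in limma and 1311 had an unadjusted p below 0.05, so the calls rest on the spread shared with the other groups. The calls of Kit, Ptcra, Dtx1, Cenpa and Fos ended when 1 of the 4 arrays was left out (adjusted p up to 0.299, for Cenpa).

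The stage score placed each sample on the scale from TN2 to TN3, and some samples lay past TN3. It was 1.38 in TN2 and 3.45 in TN3 cells (means of 2 arrays each). Young cells lay between them at 2.56 ± 0.27 (SD, n = 6), or 56.9% of the way. Old cells with competition were at 3.58 ± 0.36 (n = 6) and old cells without competition at 3.36 ± 0.09 (n = 9), close to TN3. This came mostly from the early progenitor list, whose mean was 5.12 in young cells, 4.35 with and 4.41 without competition, and 4.57 in TN3. The TN3 and beta-selection list moved less and stayed below TN3 (8.02) on average. Its mean was 7.68 in young cells, 7.93 with competition (7.81 without array 6) and 7.77 without competition. Both old groups had a higher stage score than young cells, by 1.02 (exact permutation p = 0.00216, the smallest that 6 against 6 allows, adjusted p = 0.00325) and by 0.80 (exact permutation p = 0.0002, the smallest possible, adjusted p = 0.000599). Their size depended on the background correction: they were 0.47 and 0.31 without it, and the same with the deposited log2 values. Scaling to a common median gave 1.13 and 0.48. The first difference was 1.30 on chip 2 and 0.74 on chip 4. No chip held both groups of the second. Old cells without competition were lower than those with competition by a small margin (-0.22, exact permutation p = 0.0352, adjusted p = 0.0352). Scaling to a common median made this difference -0.65 (exact permutation p = 0.0002, the smallest possible). Without array 6 of old cells with competition it was -0.077 and did not pass, and leaving out any of 7 other single arrays ended the call too.

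**Figure D1:**
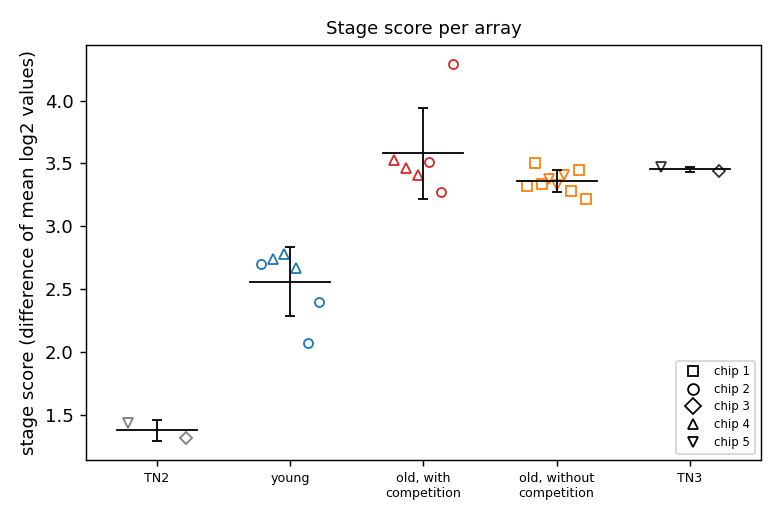
Stage score of each of the 25 arrays by group, as the mean log2 value of the TN3 and beta-selection genes minus that of the early progenitor and TN2 genes. Points are arrays with 1 symbol per chip, lines are means and bars are SD; every young array lies below every array of both old groups, and array 6 of old cells with competition is the highest at 4.29.

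Old cells with competition were set against young cells to find what differed between donor-derived cells that had stayed in the thymus and the hosts' cells. The mast cell protease gene Cpa3 fell by 3.98 ± 0.32 (log2 ± SE, n = 6 against 6, adjusted p = 2.92e-08), Hbb-b1 by 3.67 ± 0.64, the mucin gene Muc13 by 3.45 ± 0.31 and Nfe2, a transcription factor of erythroid and megakaryocytic cells, by 2.70 ± 0.31. Ikzf3, which encodes the Ikaros family factor Aiolos, rose most (3.03 ± 0.35, adjusted p = 7.81e-06), followed by Ctse, which encodes cathepsin E (2.92 ± 0.18), and Phlda1 (2.08 ± 0.33). The T cell surface receptors Cd2 and Cd28 rose by 1.86 ± 0.34 and 1.72 ± 0.28.

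In all, 454 of 15533 genes passed, 65 higher and 389 lower in old cells with competition, and 214 of them changed at least 2-fold. All 454 had the same sign on chips 2 and 4, but they were called on these same arrays, which makes this likely in advance. Over all 15533 genes the groups did not overlap in 411 (2.65%, where chance gives 0.216%), 299 of them called. The other large falls were Clec10a, a C-type lectin of myeloid cells, Alox5ap, which is needed for leukotriene synthesis, the adaptor Lat2, the class I gene H2-Q8, Igfbp4 and the interferon-induced Gvin1, which fell by 2.76 to 3.09. The other large rises were Lef1, Ptpn14, Ldhb-ps, Nrp1 and H2-Q2 (1.51 to 1.66). Beta-globin and H2-Q genes have near-identical relatives, so their probes may not tell the copies apart; 10 of the 11 probes of Hbb-b1 had the same sign. Limits of the count are that chip 2 alone gave 43 genes and chip 4 alone 235, and that array weights gave 1077 genes with 65.2% of them lower. Without array 6 there were 640 genes with 64.8% lower, against 85.7% lower with all arrays, and without array 2 or 6 of young cells 41 or 36 genes were higher rather than 65.

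**Figure D2:**
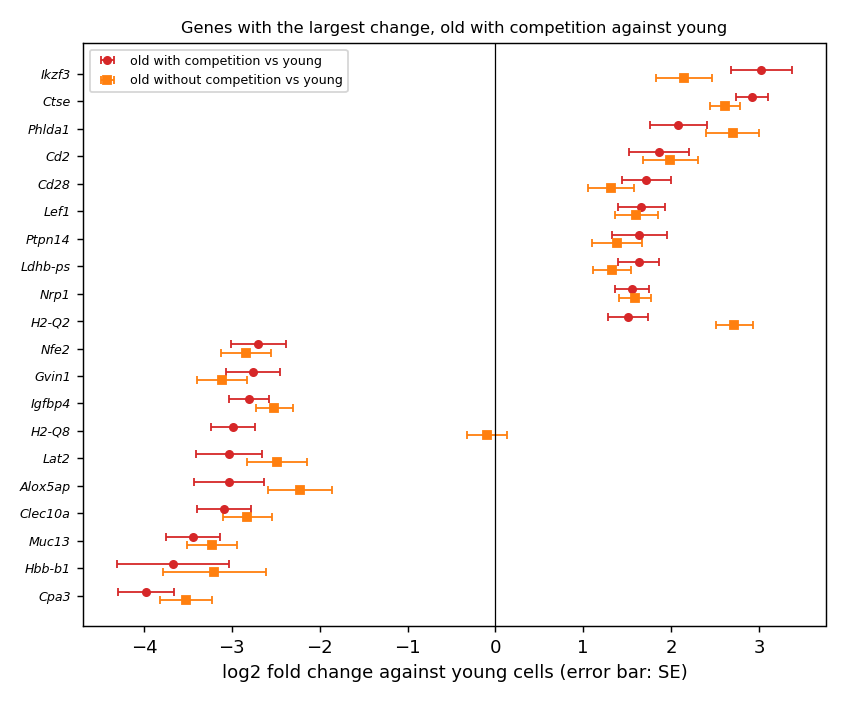
Log2 fold change against young cells (error bars, SE) of the 20 genes with the largest changes in old cells with competition (red circles, 6 against 6 arrays), with their values in old cells without competition (orange squares, 9 against 6 arrays). All 20 genes have the same sign in both, but H2-Q8 stands at -2.99 in the first comparison and -0.09 in the second.

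In this comparison 8 lists passed the set test. Of the 17 early progenitor and TN2 genes, 9 fell and 8 did not pass (9 adjusted over the list alone; adjusted p = 1.76e-19). Kit fell by 2.28 ± 0.26, Hhex by 1.81 ± 0.19 and Cd44 by 1.20 ± 0.15. The T-cell leukaemia oncogenes, which share several members with that list, had 4 of 11 lower (4 adjusted over the list alone; adjusted p = 3.85e-07), among them Lyl1 (-1.16 ± 0.15). Bcl11a and Lmo2 were detected on none of the 6 arrays of old cells and were at least 1.98-fold and 1.46-fold lower. Of the TN3 and beta-selection genes 3 rose and 2 fell (4 and 2 adjusted over the list alone), and the list as a whole was higher (adjusted p = 0.0382, or 0.423 with an estimated correlation). Its mean change was 0.26 with all arrays and 0.13 without array 6, where the call ended (adjusted p = 0.515), and it was 0.44 on chip 2, which holds that array, and 0.07 on chip 4. The call also ended without background correction (adjusted p = 0.0659). Lef1, Cd28 and the kinase gene Zap70 (1.03 ± 0.21) rose, whereas Il2ra, which lay near the floor, fell by 0.67 ± 0.17. The calls of Il2ra and Lmo2 ended when single arrays were left out (adjusted p up to 0.0771 and 0.137).

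The listed genes of antigen presentation and of the interferon response were lower in old cells with competition. The class I gene H2-Q2, which is on neither list, rose by 1.51 ± 0.23. Of 18 genes of MHC class I and peptide loading, 9 fell and 0 rose (12 adjusted over the list alone; adjusted p = 1.61e-16), among them H2-K1 by 1.01 ± 0.17, B2m, the light chain of class I molecules, by 0.48 ± 0.10, and the immunoproteasome subunit gene Psmb9 by 0.45 ± 0.09. Of 19 interferon response genes 4 fell (9 adjusted over the list alone; adjusted p = 1.15e-11): Oasl2 by 1.91 ± 0.38, Gbp2 by 1.20 ± 0.27, Gbp3 by 1.12 ± 0.18 and Irf1 by 0.79 ± 0.15. The 37 genes of both lists had a mean log2 value of 7.27 ± 0.13 (SD) in young cells and 6.62 ± 0.13 in old cells with competition (difference -0.64, exact permutation p = 0.00216, the smallest that 6 against 6 allows), and the difference was -0.67 on chip 2 and -0.62 on chip 4. TN2 and TN3 control cells were at 6.77 and 6.53, below all 6 young arrays.

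The IL-7 and STAT5 signalling list was lower with 2 of 16 members fallen (6 adjusted over the list alone; adjusted p = 0.000283): the anti-apoptotic Bcl2 by 1.57 ± 0.25 and the feedback inhibitor Socs2 by 1.81 ± 0.24. The TN2 (6.38 and 6.42) and TN3 (6.28 and 6.36) control arrays also lay below every young array (6.66 to 6.78) in the mean log2 value of this list. Of 19 myeloid and dendritic cell genes 4 fell (5 adjusted over the list alone; adjusted p = 8.09e-08): Lyz1, Lyz2, Mpo and H2-Ab1, by 1.57 to 2.03. Of 11 genes of gamma-delta T, NK and innate lymphoid cells 2 fell (4 adjusted over the list alone; adjusted p = 0.0004), Nkg7 by 2.36 ± 0.44 and Tcrg-V4 by 1.77 ± 0.43. Tcrg-V4 rested on few arrays: its change was -1.17 without array 6 of old cells with competition, and its call ended without array 2 or 4 of young cells (adjusted p = 0.0513 and 0.0613). The erythroid list did not pass (adjusted p = 0.0801), although Hbb-b1 and Hbb-b2 fell. Genes known from cell competition in other tissues had 0 of 12 members past the threshold, with none adjusted over the list alone (adjusted p = 0.418). The mitosis, DNA replication, p53 target and Bcl2 family lists did not pass (adjusted p from 0.159 to 0.998). Array 6 weighed on this: without it the mitosis, DNA replication, glycolysis and heat shock lists were higher in old cells with competition (adjusted p from 0.000212 to 0.00231) and kept the call with an estimated correlation, and the oxidative phosphorylation list was higher too (adjusted p = 0.000104, or 0.0686 with an estimated correlation). All of the 8 lists but the TN3 and beta-selection genes kept their call with an estimated correlation.

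**Figure D3:**
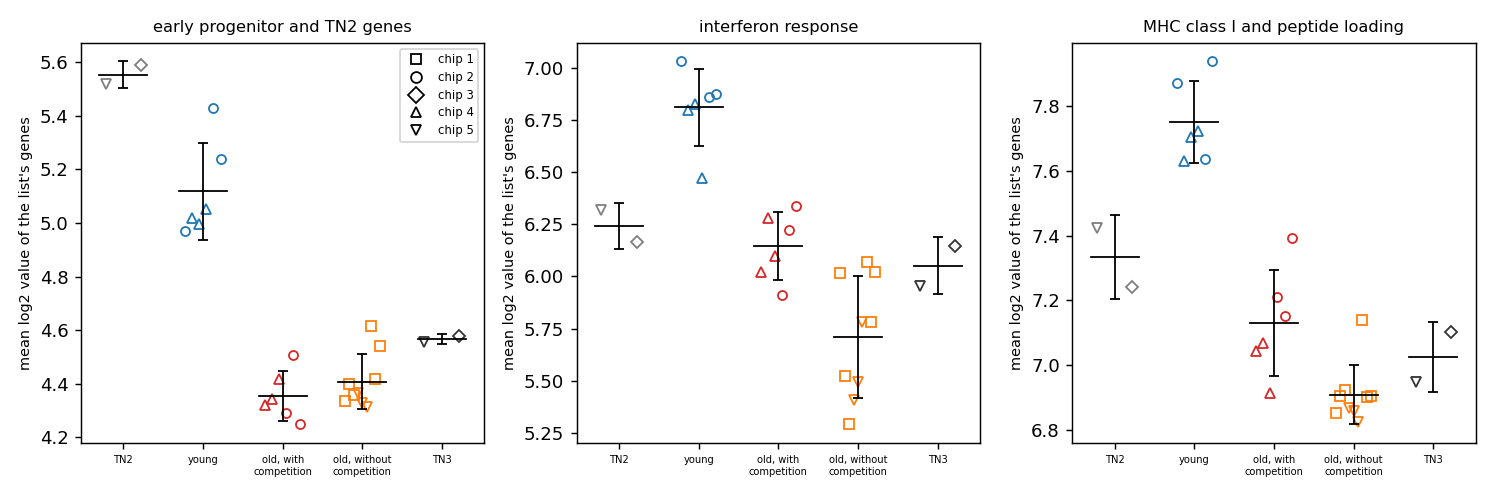
Mean log2 value per array of the measured genes of 3 lists, by group (points are arrays with 1 symbol per chip, lines are means, bars are SD). In all 3 panels every young array lies above every array of both old groups. The TN2 and TN3 arrays set the stage scale in the first panel, where every array of old cells with competition lies below both TN3 arrays. In the other panels the TN2 and TN3 arrays lie below the young arrays.

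Old cells without competition were compared with young cells in the same way. Cpa3 fell by 3.52 ± 0.30 (n = 9 against 6, adjusted p = 4.76e-08), Muc13 by 3.23 ± 0.28, Nfe2 by 2.84 ± 0.29 and Nlrc5, the transactivator of MHC class I genes, by 2.89 ± 0.32. H2-Q2 rose most (2.72 ± 0.21), followed by Phlda1 (2.70 ± 0.30), Ctse (2.62 ± 0.17) and Rsph1, a component of ciliary radial spokes (2.51 ± 0.21). Ikzf3 and Cd2 rose by 2.14 ± 0.32 and 1.99 ± 0.32. In all, 1387 genes passed, 493 higher and 894 lower, of which 333 changed at least 2-fold. Over all 15533 genes the groups did not overlap in 497 (3.20%; chance gives 0.03996%), 447 of them called. The remaining large falls were Gvin1, Clec10a, Gng2, Cd163, Igfbp4 and Lat2 (-3.11 to -2.49), and the remaining large rises Cpsf4l, BC020108, Pdgfa and the heat shock protein gene Hsph1 (1.62 to 2.33). For Lat2 and Cpsf4l 1 of 3 probes had the opposite sign, and for Cd44 1 of 7.

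The interferon response list was the most strongly lowered: 14 of 19 members fell and 5 did not pass (18 adjusted over the list alone; adjusted p = 2.15e-22). They included Rsad2 by 1.83 ± 0.24, Gbp2 by 1.74 ± 0.25, Gbp3 by 1.36 ± 0.17 and Irf1 by 1.00 ± 0.14. Of the 18 genes of MHC class I and peptide loading 11 fell (12 adjusted over the list alone; adjusted p = 4.51e-22), such as H2-K1 by 1.66 ± 0.16, H2-T23 by 1.53 ± 0.18 and Psmb9 by 0.85 ± 0.08. The 37 genes of both lists had a mean log2 value of 6.29 ± 0.17 (SD, n = 9), which was -0.97 from young cells (exact permutation p = 0.0002, the smallest possible). The early progenitor and TN2 genes had 10 of 17 lower (11 adjusted over the list alone; adjusted p = 4.87e-13), with Kit at -2.12 ± 0.24 and Hhex at -1.69 ± 0.18. The T-cell leukaemia oncogenes had 4 of 11 lower (4 adjusted over the list alone; adjusted p = 0.00101), among them Lyl1 (-1.03 ± 0.14). In the IL-7 and STAT5 list 4 of 16 fell (7 adjusted over the list alone; adjusted p = 0.000413): Socs2, Bcl2, Jak1 and Stat5a, by 0.39 to 1.52. The myeloid and dendritic cell genes had 4 of 19 lower (4 adjusted over the list alone; adjusted p = 0.00101), of which Mpo, detected on none of the 9 arrays, was at least 3.69-fold lower and H2-Ab1 fell by 2.04 ± 0.23. Scaling to a common median ended the call of the myeloid list (adjusted p = 0.223), and leaving out array 6 of young cells that of Stat5a (adjusted p = 0.0584).

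Energy metabolism and mitosis genes were higher in old cells without competition, but these calls did not hold. The oxidative phosphorylation list had 10 of 76 members higher and 0 lower (11 and 1 adjusted over the list alone; adjusted p = 0.00418, or 0.512 with an estimated correlation), among them Cox6a1 (0.47 ± 0.09) and Ndufc1 (0.64 ± 0.13). The glycolysis list had 3 of 16 higher (5 higher and 1 lower adjusted over the list alone; adjusted p = 0.0149, or 0.217 with an estimated correlation): Slc2a3, Ldha and Pfkp. The mitosis list had 3 of 21 higher (4 adjusted over the list alone; adjusted p = 0.0488, or 0.512 with an estimated correlation): Birc5, Kif11 and Aurka (0.44 to 0.52). Scaling arrays to a common median ended the glycolysis call (adjusted p = 0.592) and turned the sign of the mitosis and oxidative phosphorylation lists and of Birc5, Kif11, Aurka and Cox6a1. The calls of Ldha, Pfkp, Kif11 and Aurka also ended when single arrays were left out (adjusted p up to 0.105, for Aurka). The TN3 and beta-selection genes went both ways (4 rose, 2 fell; 5 and 5 adjusted over the list alone; adjusted p = 0.977, median -0.17, mean 0.09). Lef1, Cd28 and Ptcra were among those that rose, by 1.61 ± 0.24, 1.32 ± 0.26 and 1.07 ± 0.23. Il2ra, which lay near the floor, fell by 0.88 ± 0.16. Scaling to a common median moved the median of all genes from 0.024 to -0.17, a shift of -0.20, and gave 3950 genes, 97.1% of them lower against 64.5% lower with quantile normalization. The turned signs above came with this general drop, so they do not bear on these lists alone. No chip held both groups, the donors' strains differed, and the arrays of chip 1 alone gave 789 genes and those of chip 5 alone 898.

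The changes of both old groups against young cells were then set side by side. Of the called genes, 47 were higher and 317 lower in both comparisons, and 0 went in opposite directions. Independent lists of these sizes would share 2.06 and 22.4. Unchanged groups set against the same young arrays shared 0 in each of 100 simulations. Groups without an effect have few calls to share, so this count does not measure what the common young arrays add. The fold changes correlated across genes with r = 0.723, against 0.547 on average in those simulations (highest 0.567), and had a covariance of 0.0852 against 0.0187. With the young arrays split between the comparisons by chip, r was 0.511 or 0.543 and the covariance 0.0689 or 0.0708. No young array was then shared, so the simulated values are no measure for these. The share of genes with the same sign, 68.9%, lay within what the simulations gave (mean 68.4%, highest 69.5%). Genes are not independent replicates, so no p is given. Across genes, the change of old cells with competition followed the TN3 minus TN2 difference with r = 0.346 and that of old cells without competition with r = 0.317. Of the 454 and 1387 called genes 85.9% and 72.0% had the sign of the stage difference, against 55.8% and 56.6% of all genes.

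**Figure D4:**
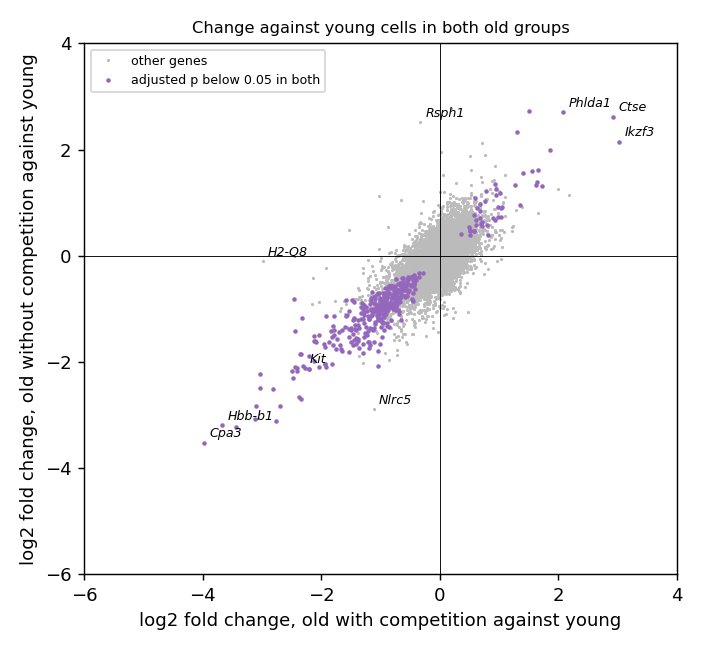
Log2 fold change of each of 15533 genes against young cells in old cells with competition (horizontal axis) and without competition (vertical axis). Purple points passed in both comparisons, 47 higher and 317 lower in both; H2-Q8, Rsph1 and Nlrc5 lie off the diagonal.

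Old cells without competition were compared directly with old cells with competition, which differ in the hosts, in the donors' strain and in the chips. H2-Q8 was higher without competition (2.89 ± 0.23, n = 9 against 6, adjusted p = 4.15e-08), as were Rsph1 (2.85 ± 0.21), Litaf (1.72 ± 0.21) and Cd200, a surface glycoprotein (1.72 ± 0.26). Ptpn7, a phosphatase of blood cells whose gene lies within 10 Mb of Ptprc, was detected on none of the arrays with competition and was at least 2.04-fold higher. Neu1, a lysosomal sialidase, fell by 1.54 ± 0.28, Spint2 by 1.26 ± 0.24, Pnrc2 by 1.20 ± 0.17 and Psmd8, a subunit of the proteasome, by 1.20 ± 0.11. In all, 193 of 15533 genes passed, 64 higher and 129 lower, 32 of them at least 2-fold. Over all 15533 genes the groups did not overlap in 110 (0.708%; chance gives 0.03996%), 77 of them called. Rnf135, Mtmr9, BC020108, Tsen34 and Fam20b rose by 0.93 to 1.68, and Fam32a, Copb1, Zfp871, Picalm, Rsf1 and Trp53inp1 fell by 1.01 to 1.14. Spint2, Psmd8 and Zfp871 each had 2 probes of opposite sign. The calls of Fam32a, Trp53inp1 and BC020108 ended when single arrays were left out (adjusted p up to 0.0937, for Fam32a).

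In this comparison 4 lists passed, and with an estimated correlation 0 of them did. The interferon response genes were lower still without competition, with 1 of 19 members, Ifi47 (-0.84 ± 0.17), past the threshold (5 adjusted over the list alone; adjusted p = 1.98e-06, or 0.0801 with an estimated correlation). Of the genes of MHC class I and peptide loading 2 rose and 4 fell (3 and 10 adjusted over the list alone; adjusted p = 0.00457, or 0.122 with an estimated correlation): Nlrc5 fell by 1.78 ± 0.32 and H2-T23 by 0.89 ± 0.18, whereas H2-Q8 and H2-Q6 (0.69 ± 0.13) rose. The TN3 and beta-selection genes were lower with Rag1 (-0.83 ± 0.19) and Tcf12 (-0.76 ± 0.16) past the threshold (2 fell and 1 rose adjusted over the list alone; adjusted p = 0.0341, or 0.433 with an estimated correlation). Array 6 of old cells with competition carried this list: its mean difference was -0.17 with it and -0.04 without it, where the call ended (adjusted p = 0.608). The oxidative phosphorylation genes were higher with 1 of 76 past the threshold, Ndufc1 (0.55 ± 0.13; 5 adjusted over the list alone; adjusted p = 0.0341, or 0.685 with an estimated correlation), and scaling to a common median turned the sign of this list and of Ndufc1. Without array 6 the call of this list ended too (adjusted p = 0.948), and without the 3 arrays that stood apart so did that of the MHC class I list (adjusted p = 0.0538). Without array 6 the DNA replication list was lower in old cells without competition (adjusted p = 0.00021, or 0.0427 with an estimated correlation), which it was not with all arrays (adjusted p = 0.976), and so were the ribosomal protein genes (adjusted p = 0.0246, or 0.421 with an estimated correlation). Of the early progenitor and TN2 genes 0 of 17 passed (adjusted p = 0.777), and of the genes known from cell competition in other tissues 0 of 12 (adjusted p = 0.976). In the IL-7 and STAT5 list, which did not pass (adjusted p = 0.579), Stat5b fell by 0.86 ± 0.19 and Jak1 by 0.43 ± 0.11. The calls of Jak1, Stat5b, Ndufc1 and Rag1 ended when single arrays were left out (adjusted p up to 0.123, for Jak1). The count rested on few arrays: it was 343 without array 6 and 115 without array 4 of old cells with competition, 132 (85 of them lower) without array 1, 57 with the arrays of chip 5 alone and 577 with array weights. Scaling to a common median moved the median of all genes from 0.021 to -0.20, a shift of -0.22, and gave 3425 genes, 98.8% of them lower against 66.8% with quantile normalization.

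Since old cells with competition carry CD45.1 and young cells CD45.2, called genes near Ptprc were counted. Of 97 tested genes within 10 Mb of Ptprc 9 were called, or 9.28%, against 3.02% of the other genes with a known place (odds ratio 3.29, two-sided Fisher exact p = 0.00287). They included Ctse and Ptpn7, which was detected on none of the 6 arrays of old cells with competition and was at least 4.6-fold lower. The planned windows of 5 Mb and 20 Mb gave odds ratios of 3.33 (Fisher exact p = 0.0226) and 2.30 (Fisher exact p = 0.0184). Without the 3 arrays that stood apart, 630 genes were called in all and 7 near Ptprc. The odds ratio was then 1.77 and did not pass (Fisher exact p = 0.131). For old cells without competition, from F1(WB x B6/Ly5.1) donors, 11 of the 97 genes were called against young cells (odds ratio 1.26, Fisher exact p = 0.479), and 4 in the direct comparison (odds ratio 3.39, Fisher exact p = 0.0354).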

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

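The tests of myeloid genes, of the level against TN3 cells, of the TN2 share with genes from 1 TN pair and with the fixed lists, of the stage shift, of the strain or host, of the chip for the interferon genes and, in the direct comparison, of the stage of cells, of 1 chip alone, of chips within groups with limma, of calls chosen without the chip 5 arrays and of further probes within classes of fold were chosen only after the result was seen; the others were chosen before. Each value below is an array whose gap to the nearest array of its group was larger than the 95% limit of Dixon's test. Chance alone would pick about 1 in 20 groups; here 44 values were picked in 336 groups tested, and 29 of them were on array 6 of old cells with competition.

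On array 6 of old cells with competition, 2304 genes lay over 1 log2 unit from the group, and the stage score was 4.29. Its mean log2 value was 8.54 for the TN3 and beta-selection genes, 5.01 for the T-cell leukaemia oncogenes, 6.80 for mitosis, 7.84 for oxidative phosphorylation and 6.69 for glycolysis. Genes of T cells and recombination that stood apart there were Cd2 (8.77), Cd28 (8.44), Ptprc (8.65), Rag1 (11.1), Rag2 (6.84), Dtx1 (5.01), Tcrg-V4 (4.14) and Ptpn7 (4.23). Genes of survival, growth and stress were Bcl2 (5.89), Cdkn1a (4.16), Trp53inp1 (10.3), Birc5 (8.43), Hsph1 (6.48), Ldha (9.18), Atp5j (9.03), Uqcr10 (9.30) and Rpl29 (7.84). The remaining genes were Ctse (8.27), Gbp3 (4.85), Lat2 (5.99), Ldhb-ps (10.13) and Rnf135 (4.10).

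Single values on other arrays also stood apart. In old cells with competition these were Hbb-b1 on array 1 (6.77) and Clec10a on array 2 (4.76). In old cells without competition, array 1 had 798 genes over 1 log2 unit from the group and stood apart for Psmb9 (8.83), Tsen34 (6.63) and Ldha (11.2). Others in that group were Ndufc1 on array 3 (8.95), Rsf1 on array 4 (4.75), Clec10a on array 6 (6.02), the MHC class I and peptide loading list on array 7 (7.14) and Cd163 on array 8 (4.97). In young cells, B2m on array 3 (10.13) and, on array 5, the myeloid and dendritic cell list (5.20), Alox5ap (8.56) and Zfp871 (7.46) stood apart.

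The lower early progenitor genes in old cells did not come from array 6 alone, since 7 of the 9 members that fell with competition still passed without it. Myeloid cells among the young cells cannot be told apart from a change within the cells, although the sort for CD25 would remove most of them. Of the myeloid list 21.1% fell, but 13 of its 19 members lay near the floor in young cells and could not fall. Of the other 6 members, 4 fell. Among these 4, Lyz1, Lyz2 and Mpo had a higher mean in TN2 cells than in young cells, and H2-Ab1 had a lower one. A smaller share of TN2 cells stays open too, although the genes higher in TN3 rose by a median of 0.11 (SE 0.022) against 0.38 predicted (difference -0.27), and by 0.16 (SE 0.023) against 0.24 or 0.13 (SE 0.055) against 0.30 with genes from 1 TN pair and the profile from the other, each more than 2 SE below, which was the bound set beforehand. That bound left out the error of the prediction, which rests on 2 arrays per TN group and varied between pairs (SD 0.043), and with the fixed lists the TN3 genes rose by 0.26 (SE 0.13) against 0.27 or 0.36 predicted, or without array 6 by 0.13 (SE 0.042), 1.78 or 2.23 combined SE below; a smaller share alone could bring the early progenitor list no lower than TN3 cells, yet it was lower in old cells with competition (-0.21, SE 0.099; 4.25 to 4.51 against 4.56 and 4.58 in TN3) and Kit was at 4.62 against 5.69, but 15 of the 17 members lay near the floor in TN3 cells, whose 2 arrays were on other chips. The age of the cells and competition, which the design names, stay open and untested.

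The lower interferon and MHC class I genes in old cells were not explained by the shift from TN2 to TN3 cells, since their median change with competition was -0.58 and still -0.52 after that shift was taken away. For old cells with competition the chip is argued against as well, because the mean change was -0.67 on chip 2 and -0.62 on chip 4; for old cells without competition (-0.92 and -1.08 on chips 1 and 5) it cannot be told apart from the group, since no chip held both. The strain or host of the young cells is a candidate explanation: TN2 and TN3 control cells, which share the B6/Ly5.1 background of the old cells with competition and were in no transplanted host, also lay below young cells (by -0.50 and -0.74), though on other chips. The high value may thus belong to the young cells rather than the low value to the old ones, and age and competition stay open and untested.

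The differences between old cells without and with competition were not explained by the stage of the cells, since 55.4% of the called genes had the direction of TN3 minus TN2. An effect of 1 chip alone is argued against, since of the 100 genes with the smallest p between 1 chip of each group 79.0% to 90.0% kept their direction on the other chips (55.0% to 59.1% of all genes), and chips 1 and 5 differed in 0 genes in limma (877 at an unadjusted p below 0.05). An effect that chips 1 and 5 share cannot be told apart from the group, because no chip held both: 75.1% of the 193 calls, chosen with these arrays, had the same direction within chip 5 against the TN3 array, where over 75% was set beforehand to argue against the chip, but of calls chosen without the chip 5 arrays 65.1% did, as did 57.8% of all genes, and the 98.2% of the latter calls that kept their direction on the chip 5 arrays against old cells with competition compare across chips. Strain variants under single probes are a candidate explanation. Further probes of called genes moved with the call at an unadjusted p below 0.05 in 29.8%, against 63.3% for old cells with competition against young. The Fisher exact p was 1.57e-10, and the exact conditional p within classes of fold was 2.07e-05. Both treat the probes of a gene as independent. By sign alone, all probes agreed in 54 of 85 called genes with several probes, against 179 of 200 for old cells with competition against young. The hosts and competition stay open and untested.

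Other splits of the arrays into groups of the same sizes were fitted, 100 for each comparison with the real one included, with the chip correlation from a subset of genes. The real split gave 450 genes for old cells with competition against young, and the highest other split 21. It gave 1421 for old cells without competition against young, the highest other split 236, and 204 for the direct comparison, the highest other split 8. In each case 1 of the 100 splits, the real one, gave as many genes, which is the smallest share that 100 splits can give. Splits that mix arrays of groups that differ have a wider spread, and so give few genes. The counts are thus unlikely for arrays assigned to groups at random. The splits cannot speak to mice shared between samples or, for old cells without competition, to the chip. Chip 2 against chip 4, with the group as a term, gave 0 genes in limma (1255 at an unadjusted p below 0.05).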

How the results depend on the processing

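Leaving out the 3 arrays that stood apart, testing lists without array 6 of old cells with competition and adding the Xist class of each array as a term were chosen after seeing the data; the other alternatives were planned. No paired analysis was possible because the labels give no replicate numbers and do not say which host a sample came from; whether young cells and old cells with competition, whose positions alternate on chips 2 and 4, shared hosts is not stated, and their samples were treated as independent; arrays are numbered within a group in the deposited order. Of the values of named genes under the alternatives, 4913 kept direction and side of the threshold, 336 kept direction but no longer passed, 6 newly passed and 28 reversed. Counts of genes stayed within 1.5 times under no background correction, the deposited log2 values, other filters, the mean over probes and other variance models. Where results changed, the cause was not tested unless stated.

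Scaling to the common median gave 3950 genes without competition against young, 3425 without against with and 84 for TN3 against TN2, and 8 lists in the direct comparison. Against young it reversed Atp5j (-0.10), Aurka (-0.091), Birc5 (-0.014), Cox6a1 (-0.017), Kif11 (-0.012), Uqcr10 (-0.0087), Rag2 (-0.16) and the mitosis and oxidative phosphorylation lists (adjusted p = 0.959 and 0.230). In the direct comparison it reversed Cd44 (-0.011), Kit (-0.0055), Ndufc1 (-0.0039) and the oxidative phosphorylation list (adjusted p = 0.0169). In TN3 against TN2, Ptprc reversed with it (-0.22) and with the mean over probes (-0.17).

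With an estimated correlation, 0 lists passed in the direct comparison and 4 in TN3 against TN2, and with fry 2 and 5. Chip 2 alone gave 43 genes with competition against young and chip 4 alone 235, with Ptprc (-0.060) and Rag2 (-0.16) reversed. The arrays of chip 1 alone gave 789 genes without competition against young, and reversed Rag2 in the direct comparison (0.056). Those of chip 5 alone gave 898, with Rag2 reversed (-0.43), and 57 in the direct comparison. These settings use fewer arrays. Fitting only the arrays of the groups compared gave 2142 genes without competition against young and 0 for TN3 against TN2 (limma without a chip block; 1311 at an unadjusted p below 0.05). Array weights gave 1077, 2167, 577 and 82 genes in the order of the comparisons with and without competition against young, the direct one and TN3 against TN2, and reversed Rag2 with competition against young (-0.10) and in the direct comparison (0.10). The correlation of both changes was 0.511 and 0.543 with the young arrays split.

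Without the 3 arrays the direct comparison gave 400 genes, 2 lists and a stage difference of -0.072 (exact permutation p = 0.201), TN3 against TN2 gave 366 genes, the odds ratio near Ptprc was 1.77, and Rag2 reversed with competition against young (-0.14) and in the direct comparison (0.14). With the Xist term, Cd44 reversed in the direct comparison (-0.011) and 2 lists passed. Leaving out 1 array at a time, the direct comparison gave 115 to 343 genes and a stage difference of -0.28 to -0.077. With competition against young, Il2rg ranged from -0.47 to 0.018 and Rag2 from -0.14 to 0.37. Rag2 ranged from -0.066 to 0.13 without competition against young and from -0.32 to 0.19 in the direct comparison, and Ptprc from -0.19 to 0.25 in TN3 against TN2, where the lone array was assumed to vary like the other groups. Signal near the floor, as for Rag2 and Il2ra, limits what these arrays resolve.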

Other observations

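The tests of double-positive markers and of T cell receptor genes and the count in the MHC region were chosen only after the result was seen. Array 6 of old cells with competition might hold cells past the TN stages, which the sort against CD4, CD8 and CD3 would remove. Of the 7 measured genes of the double-positive and mature T cell list, 3 (42.9%) were above the highest other array of the group: Cd4 (8.86 against a mean of 4.89), Cd6 (10.01 against 7.65) and Cd69 (6.98 against 5.49). All 9 measured T cell receptor alpha genes were above the highest other array too, among them Trav9n-4 (10.76 against 6.43), TRAC (7.31 against 4.36) and Trav14n-3 (6.98 against 4.83), and all 4 gamma genes were below the lowest, with Tcrg at 4.28 against 8.88. These go with such cells. Of the double-positive and mature T cell list, however, Cd8b1 (6.54 against 7.77) and Ctla4 (4.12 against 6.42) were below the lowest other array. Ccr7 and Foxp3 lay within the range of the other arrays, so the tests left this open. These genes are named because of their values on this array.

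Called genes near Ptprc may come from the strain of the CD45.1 allele. Of the 9, 77.8% had the same direction between the B6/Ly5.1 control cells and young cells, but so did 76.9% of the calls outside the window (Fisher exact p = 1), so the test does not separate the window from the other calls. Ctse was at 4.68 in young, 7.59 and 7.29 in old cells with and without competition, 8.04 in TN2 and 7.75 in TN3 cells. Ptpn7 was at 6.44, 4.12, 5.27, 4.15 and 4.09 in these groups, and Kdm5b at 7.20, 5.98, 6.60, 5.84 and 5.85. For both, cells of F1(WB x B6/Ly5.1) donors lay between young and B6/Ly5.1 cells. Atp2b4, Nuak2, Rgs1 and Timm17a had the opposite direction between TN2 and young cells. These levels were read after the result was seen, and no test separated strain from competition.

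In the region of the MHC genes, 12 of 101 tested genes were called with competition against young (odds ratio 4.36, Fisher exact p = 5.88e-05), 22 without competition against young (odds ratio 2.77, Fisher exact p = 0.000162), 8 in the direct comparison (odds ratio 6.93, Fisher exact p = 4.38e-05) and 1 in TN3 against TN2 (odds ratio 0.820, Fisher exact p = 1). This region was taken as the stretch from H2-K1 to H2-T23. Apart from TN3 against TN2, its calls include members of the MHC class I list, such as H2-K1 and Psmb9. The counts are thus no separate evidence beside that list, and the Fisher test treats neighbouring genes as independent. Of 6092 unnamed probes, 58, 227, 58 and 48 passed in the same comparisons. Xist was above log2 6 on 3 young arrays, all on chip 2, and on 2 arrays of old cells with competition, both on chip 4; all 13 interferon and MHC class I genes that fell still passed with the Xist class as a term.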
